A study of Arabidopsis thaliana with 12 samples.

How the data were processed

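RNA from the aerial parts of 18-day-old Arabidopsis plants was measured on 12 Affymetrix ATH1 arrays, 3 for each of 4 groups: the rice LBD37 over-expressing lines K16331 and K19624 and their empty vector controls EV_T2 and EV_T3. Per the labels, 10 µg of total RNA per array was turned into biotin-labelled cRNA. The values deposited by the authors are probe set signal intensities on a linear scale, 1 per probe set and array. They had been scaled by the authors so that the mean without the top and bottom 2% was almost equal on all arrays. The algorithm that summarised the probes is not given in the sources used here. The table holds 22810 probe sets; 64 array controls were left out of the tests and used for RNA quality only, and 22746 were tested.

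Intensities below the 20th percentile of all values (21.8) were raised to it, since values near background vary widely on a log scale, and all values were log2 transformed to a floor of 4.45. Between 17.8% and 21.7% of the values of an array lay at that floor. A fold change is given as at least that size where an array of the lower group lies at the floor, and log2 fold changes of such genes are bounds likewise. No further normalization between arrays was made. Array medians lay between 173 and 188, and the highest signal was 37729. Probe sets are named by the single gene that the platform table pairs with them, which 13513 have; 503 were paired with several genes and 8730 with none. Of the single genes, 13436 matched the reference gene table, and 13355 genes had a main probe set, the brightest where a gene had several (147 genes).

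Differences were tested in R 4.3.3 with limma 3.58.1, by lmFit on all 12 arrays with a mean per group (8 residual degrees of freedom) and eBayes. All tests were two-sided. The contrasts were each line minus its own control, the mean of these 2 effects, their difference, and EV_T3 minus EV_T2. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets within a contrast, and a probe set was called at an adjusted p under 0.05. Errors beside fold changes are standard errors of the model; errors beside signals are standard deviations over 3 arrays. Counts shared by both lines were set against the number expected if the lists were independent.

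The contrasts, the threshold, the alternatives and 19 gene lists were chosen before the data were examined. These lists hold 382 genes, of which 51 had a named probe set; 6 lists had none and 8 had at least 3, the minimum for a list test. Because so few members were named, 22 lists were added from the gene names alone, once the names were known and before any difference was computed. Lists were tested with limma camera at a preset correlation of 0.01 between genes. Their p-values were adjusted by Benjamini-Hochberg over the 8 lists and, separately, over the 22 added lists within a contrast; the plan had named 1 adjustment over the lists. Each list test was repeated with the correlation estimated from the data. In 150 list tests the sign of the median, the mean and the test differed in 35, and in 0 of those called. The genes of each fixed list were also adjusted over the list alone.

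Genes named in the text follow a rule set beforehand among genes with a named probe set, with exceptions stated. For each line they are the 10 largest called rises and 10 largest called falls in which all 3 arrays of the line lie beyond all 3 control arrays. They are the 8 and 8 largest for both lines together and, with that condition met in each line, for the mean effect. For the difference and for the 2 controls they are the 6 and 6 largest, and for each list the 4 smallest p-values. Exact permutation tests were used for single values compared between groups, where 3 against 3 arrays give no two-sided p under 0.1.

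The alternatives were a fit of each line with its own control only, the replicate number as a block, eBayes with trend and robust settings, array weights, quantile normalization, a common median, and removal of probe sets below the 40th percentile of mean signal. Floors at the 5th percentile (2.67) and the 40th percentile (95.1), a minimum of 2-fold, an ordinary linear model and leaving out each array in turn were also run. For lists, estimated correlation, a variance trend, the mean of all probe sets of a gene and the limma test fry were run. The model was tested on simulated data with 50 changed probe sets at each of 4 sizes among 22746. The changed ones were drawn only from probe sets with a mean log2 signal over 2 above the floor. The shares recovered therefore do not cover dimmer ones. The model recovered 36% at 1.5-fold, 78% at 2-fold, 100% at 4-fold and 100% at 8-fold for K16331, with 13 false calls among 170. For K19624 it recovered 22%, 78%, 96% and 94%, with 14 false calls among 159. A list shifted on purpose was called, as was 1 of 29 others. The simulated spread was independent between genes, so this list check does not cover lists of correlated genes. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.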

Results

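Transcript levels were measured in the aerial parts of Arabidopsis thaliana plants carrying the rice gene LBD37, which encodes a protein with a lateral organ boundaries domain, under a full-length cDNA over-expression (FOX) construct. Line K16331 was sampled as T2 plants grown on medium with 20 mg/l hygromycin, with 2 plants per array, and line K19624 as homozygous T3 plants, with 1 plant per array and no hygromycin named for the medium. Each line had its own empty vector control of the same generation, called EV_T2 and EV_T3 here. EV_T3 arrays held 1 plant each, and the number of plants per EV_T2 array is not stated. All plants were 18 days old. The 12 Affymetrix arrays fall into 4 groups of 3. The number of arrays limits the precision, and how far signal near background limits it was not isolated. Since nothing states that the plants came from separate cultures, p-values measure only the spread between these samples. The array carries Arabidopsis probe sets, so the rice transcript itself was not measured. The 6 Arabidopsis class II LBD genes were not analysed here because no probe set was paired with them. The median signal of an array lay between 173 and 188. Correlations of log2 signal between arrays of 1 group ranged from 0.980 to 0.991, and averaged 0.964 between K16331 and EV_T2 and 0.976 between K19624 and EV_T3.

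K16331 was compared with EV_T2 to ask which transcripts differ when rice LBD37 is over-expressed. OSM34 (AT4G11650), which encodes an osmotin-like protein, had a log2 signal of 12.95 ± 0.61 in K16331 and 5.03 ± 0.80 in EV_T2 (SD, n = 3). AT4G16260, a β-1,3-glucanase family gene, was at least 61.0-fold higher in K16331, and CHI (AT2G43570), a chitinase family gene, 31.9-fold higher. AT1G66100, a member of the thionin family of antimicrobial peptides, fell at least 147-fold, from a geometric mean signal of 4989 in EV_T2 to 33.9 in K16331, where 1 of 3 arrays lay at the signal floor. EXPA8 (AT2G40610), an expansin that loosens cell walls, and COR15B (AT2G42530), a cold-regulated chloroplast protein gene, fell 3.99-fold and 5.27-fold.

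In all, 1630 probe sets were higher and 1954 lower in K16331 among 22746 tested, of which 621 and 333 differed at least 2-fold. By limma with Benjamini-Hochberg adjustment, the log2 fold change was 7.93 ± 0.70 (SE) for OSM34 (adjusted p = 5.1e-04) and -7.20 ± 0.44 for AT1G66100 (adjusted p = 1.1e-04), with all 3 K16331 arrays on 1 side of all 3 EV_T2 arrays for both genes. The other large rises were AT4G22470 (log2 signal 11.37 against 6.37), AT3G46280 (log2 fold change 4.94), AT3G02480 (4.85), AT3G18250 (4.56), the amylase gene AMY1 (4.21), AT5G39520 (4.09) and the sugar transporter family gene AT3G05400 (3.82). The other large falls were AT1G29270 (log2 fold change -2.90), AT5G02540 (-2.83), AT3G62950 (-2.62), Fes1B (-2.56), AT3G05730 (-2.41), AT3G49160 (-2.41), the methionine sulfoxide reductase gene MSRB6 (-2.33) and AT2G05160 (-2.20). OSM34 was also bright in both T3 groups, at a log2 signal of 12.76 ± 0.52 in K19624 and 11.90 ± 1.37 in EV_T3 (SD, n = 3), and AT4G16260 likewise at 11.13 ± 1.49 and 11.16 ± 1.26. AT4G22470, AT3G18250, AT5G39520 and AT3G05400 were also higher on every EV_T3 array than on any EV_T2 array. Their lowest EV_T3 signals were 8.21, 7.89, 8.78 and 7.09, against highest EV_T2 signals of 8.05, 6.19, 6.54 and 5.78 (log2). For CHI, AT3G46280 and AMY1 only EV_T3 replicate 3 lay within the EV_T2 range. For AT3G02480 all EV_T3 arrays did. Of the falls, Fes1B, AT1G29270, AT3G62950, AT3G05730, COR15B and AT2G05160 were also lower on every EV_T3 array than on any EV_T2 array. The highest EV_T3 signals were 8.36 for Fes1B and 11.04 for AT3G05730, against lowest EV_T2 signals of 10.27 and 12.4 (log2). For AT5G02540, AT3G49160 and AT1G66100 the 2 controls overlapped, and MSRB6 was higher on every EV_T3 array. EV_T3 carries no rice LBD37. Without EV_T2 replicate 1 the counts dropped to 1006 higher and 1025 lower, and fitting only the 6 arrays of this comparison gave 1227 lower. The lower count was 1166 without K16331 replicate 3 and 1176 without EV_T2 replicate 2. Of the 20 genes with the largest changes, 10 were called under every alternative and with each array left out, OSM34, AT4G16260 and AT1G66100 among them. AT1G29270 and AT2G05160 were called wherever they were run, which excludes the setting without dim probe sets. The 6-array fit ended the calls of AT3G02480 (limma adjusted p = 0.090), AT3G62950 (0.068) and AT3G05730 (0.068), and a higher signal floor those of AT3G02480 (0.0503) and AT3G49160 (0.089). MSRB6 was not called when K16331 replicate 2 or 3 or any EV_T2 array was left out (limma adjusted p from 0.053 to 0.074).

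Among gene groups fixed before the data were examined, 3 of 5 measured senescence genes rose in K16331, namely the sugar transporter gene SAG29 (log2 fold change 3.51 ± 0.88, SE), the pyruvate phosphate dikinase gene PPDK (1.07 ± 0.20) and the transcription factor gene WRKY6 (1.05 ± 0.22). The count was also 3 adjusted over the list alone. The senescence list as a whole was shifted up by the limma camera test with Benjamini-Hochberg adjustment (adjusted p = 0.011; adjusted p = 0.24 with an estimated correlation). Of 4 genes of the cold, drought and abscisic acid list, COR15A (-1.25 ± 0.30) and COR15B (-2.40 ± 0.38) fell, 2 also when adjusted over the list alone. By limma camera the list did not pass (adjusted p = 0.30). Of 10 photosynthesis genes, the antenna protein gene LHCB4.3 rose (1.69 ± 0.14) and 9 did not pass; adjusted over the list alone, 1 rose and 1 fell. Of 3 jasmonate genes, the thionin gene THI2.1 rose (1.97 ± 0.37), 1 also when adjusted over the list alone. None of 6 anthocyanin, 6 heat shock, 6 starch and sugar or 3 root marker genes passed over all probe sets. Adjusted over the list alone, 2 starch and sugar genes fell and none of the others changed. None of these lists passed as a whole by camera, the photosynthesis and jasmonate lists included (adjusted p from 0.23 to 0.71). GI, the measured gene of the circadian clock list, fell (-0.76 ± 0.16, limma adjusted p = 0.013). PPDK, THI2.1, COR15A, COR15B and GI also changed in the same direction in EV_T3 against EV_T2, which both lack rice LBD37, with values given below. SAG29, WRKY6 and LHCB4.3 were not called there. The 7 measured genes of the nitrate uptake, amino acid metabolism, glucosinolate and cell division lists, NRT2.5, AT2G26690, ASPGA1, UGT74B1, BCAT4, AUR1 and AUR2, did not pass by limma (adjusted p from 0.13 to 1).

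Of the 22 gene groups added once the probe names were known, 6 shifted in K16331, and none did with an estimated correlation. In the chlorophyll synthesis group 5 of 9 genes fell, among them the protochlorophyllide reductase gene PORB (log2 fold change -1.49 ± 0.15, SE) and the uroporphyrinogen decarboxylase genes HEME1 (-0.86 ± 0.13) and HEME2 (-0.66 ± 0.10). Its camera adjusted p after Benjamini-Hochberg in limma was 2.5e-04 (adjusted p = 0.29 with an estimated correlation). Among 51 UDP-glycosyltransferase genes 10 rose, including UGT84A3 (1.61 ± 0.20) and GT72B1 (1.66 ± 0.24), and 3 fell, including UGT80B1 (-0.74 ± 0.12), with adjusted p = 0.0019 and adjusted p = 0.29 with an estimated correlation. Of 16 SWEET sugar transporter genes 5 rose, including SWEET7 (1.77 ± 0.35) and SWEET10 (1.75 ± 0.41), with adjusted p = 0.019 and adjusted p = 0.30 with an estimated correlation. Of 11 iron homeostasis genes 4 rose, including bHLH115 (0.62 ± 0.05), and bHLH121 fell (-0.60 ± 0.11), with adjusted p = 0.038 and adjusted p = 0.37 with an estimated correlation. The 15 mitochondrion-encoded genes shifted up with no single gene passing (adjusted p = 0.019; adjusted p = 0.31 with an estimated correlation). The 19 plastid-encoded transcription and translation genes shifted down, with rpl16 alone passing (-0.35 ± 0.10; adjusted p = 0.024; adjusted p = 0.51 with an estimated correlation). Without K16331 replicate 2 the SWEET, iron, mitochondrial and plastid groups did not pass by camera (adjusted p from 0.10 to 0.11). The iron and plastid groups also failed without EV_T2 replicate 1 (0.083 and 0.088) and the mitochondrial group without EV_T2 replicate 3 (0.062). Without dim probe sets none of these 4 groups passed by camera (adjusted p from 0.089 to 0.11). The SWEET call also ended with array weights (0.052), the iron call with a lower signal floor (0.063) and the mitochondrial call with the mean of all probe sets of a gene (0.052). By the limma test fry the mitochondrial (adjusted p = 0.058) and plastid (0.12) groups did not pass. In EV_T3 against EV_T2, which both lack rice LBD37, the UDP-glycosyltransferase group also shifted up and the plastid group down. The other groups named here did not pass there.

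K19624 was compared with EV_T3 to ask the same of an independent line. The peroxidase family gene AT4G30170 was at least 21.2-fold higher in K19624, with a log2 signal of 9.73 ± 0.56 against 5.32 ± 0.91 in EV_T3 (SD, n = 3), and PAP85 (AT3G22640), a vicilin-like seed storage protein gene, was 19.6-fold higher. The sugar transporter family gene AT5G18840 rose 10.8-fold, GH3.3 (AT2G23170), which encodes an enzyme joining auxin to amino acids, 6.08-fold. The copia-like retrotransposon AT4G16870 rose from a log2 signal of 6.20 ± 0.12 to 8.65 ± 0.17. EV_T3 was the low group for this gene, which ran from 9.56 to 9.88 in EV_T2 and from 8.93 to 9.11 in K16331. AT1G66100 fell here too, 18.5-fold, from a geometric mean signal of 4847 to 262. COR15A (AT2G42540) fell 7.83-fold, MSRB6 7.68-fold, EXPA8 5.73-fold and the response regulator gene ARR15 4.09-fold.

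In this line 444 probe sets were higher and 408 lower, with 135 and 107 at least 2-fold. By limma with Benjamini-Hochberg adjustment, the log2 fold change was 2.46 ± 0.11 (SE) for AT4G16870 (adjusted p = 4.8e-05), 4.41 ± 0.45 for AT4G30170 (adjusted p = 0.0033) and -4.21 ± 0.44 for AT1G66100 (adjusted p = 0.0036), with all 3 K19624 arrays on 1 side of all 3 EV_T3 arrays for each. The receptor kinase gene AT1G51850 was at the signal floor on all EV_T3 arrays and at least 5.07-fold higher in K19624. The other large rises were AT2G31730 (log2 fold change 2.54), AT5G62730 (2.45), AT5G39220 (2.39) and the pseudogene AT2G04460 (2.33), and the other large falls were AT1G13650 (-2.45), AT3G19620 (-2.06), AT4G02850 (-1.91), AT1G20030 (-1.89) and AT5G45950 (-1.88). When any K19624 array or EV_T3 replicate 2 or 3 was left out, the counts fell to between 170 and 294 higher and between 163 and 262 lower. A lower signal floor gave 277 and 246, and a fit of only the 6 arrays of this comparison 60 and 68. Of the 20 genes with the largest changes only AT4G16870, AT5G18840 and EXPA8 were called under every alternative and with each array left out. AT5G39220 was called wherever it was run, which excludes the setting without dim probe sets. The 6-array limma fit ended 14 of the 20 calls: AT4G30170 (adjusted p = 0.069), PAP85 (0.059), GH3.3 (0.084), AT1G66100 (0.058), AT2G31730, AT5G62730, AT2G04460, MSRB6, AT1G13650, AT3G19620, ARR15, AT4G02850, AT1G20030 and AT5G45950 did not pass. AT1G51850 did not pass in limma with a higher signal floor (adjusted p = 0.517). MSRB6 did not pass without K19624 replicate 2 (0.065), EV_T3 replicate 2 (0.059) or EV_T3 replicate 3 (0.080).

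Of 4 cold, drought and abscisic acid genes, COR15A (log2 fold change -2.97 ± 0.30, SE) and COR15B (-1.68 ± 0.38) fell in K19624, 2 also when adjusted over the list alone. The list shifted down by camera in limma with Benjamini-Hochberg adjustment (adjusted p = 6.8e-04; adjusted p = 0.24 with an estimated correlation). Of 10 photosynthesis genes LHCB4.3 rose (0.74 ± 0.14) and LHCB4.1 fell (-0.20 ± 0.04), and adjusted over the list alone 1 rose and 6 fell. The photosynthesis list shifted down (adjusted p = 0.0030; adjusted p = 0.40 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.45) and without dim probe sets (0.052), with a variance trend (0.0504) and by fry (0.11). None of the 6 anthocyanin or 5 senescence genes passed, over all probe sets or adjusted over the list alone. By camera the anthocyanin list shifted down (adjusted p = 0.024; adjusted p = 0.55 with an estimated correlation) and the senescence list up (adjusted p = 0.024; adjusted p = 0.29 with an estimated correlation). The anthocyanin list did not pass by camera without dim probe sets (adjusted p = 0.12) or in a fit of these 6 arrays alone (0.087), nor by fry (0.33). It did not pass without K19624 replicate 1 (0.10), EV_T3 replicate 2 (0.10) or EV_T3 replicate 3 (0.45), nor the senescence list without K19624 replicate 2 (0.062), EV_T3 replicate 1 (0.069) or EV_T3 replicate 3 (0.067). None of 6 starch and sugar, 3 jasmonate, 6 heat shock or 3 root marker genes passed, 0 also when adjusted over the list alone, and neither did their lists by camera (adjusted p from 0.14 to 0.87). The 8 measured genes of the nitrate uptake, amino acid metabolism, glucosinolate, circadian clock and cell division lists did not pass by limma (adjusted p from 0.12 to 1).

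Of the 22 added groups 3 shifted in K19624 by camera in limma with Benjamini-Hochberg adjustment, with no single member passing. The 35 plastid-encoded photosynthesis genes shifted down, with rbcL at -0.98 ± 0.36 (log2, SE) and psbC at -0.80 ± 0.28 (adjusted p = 0.0013; adjusted p = 0.76 with an estimated correlation). The 9 chlorophyll synthesis genes shifted down, with PORB at -0.47 ± 0.15 and HEME1 at -0.40 ± 0.13 (adjusted p = 0.0058; adjusted p = 0.72 with an estimated correlation), a call that ended without K19624 replicate 2 (0.079). By the limma test fry neither the plastid group (adjusted p = 0.30) nor the chlorophyll group (0.12) passed. The 13 endoplasmic reticulum stress genes shifted up, with ATERDJ2A at 0.29 ± 0.08 and DER1 at 0.22 ± 0.06 (adjusted p = 0.0080; adjusted p = 0.33 with an estimated correlation). The log2 difference between 3 prime and 5 prime control probe sets, a measure of RNA quality, was 0.54 ± 0.04 in K19624 and 0.44 ± 0.03 in EV_T3 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). It was 0.40 ± 0.01 in K16331 and 0.41 ± 0.05 in EV_T2 (exact permutation p = 0.9).

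Genes called in both lines, which share no array, were examined next. Among named genes, those higher in both were AT5G18840 (log2 fold change 2.80 ± 0.33 in K16331 and 3.43 ± 0.33 in K19624, SE), AT1G51850, AT2G04460, AT2G31730, the β-glucosidase gene BGLU45, AT5G22460 (3.39 ± 0.14 and 1.94 ± 0.14), AT1G51790 and AT4G30170. A probe set paired with no gene, given below, rose more than AT5G18840, by 4.02 ± 0.20 and 4.56 ± 0.20. Lower in both were AT1G66100, MSRB6, AT1G13650, EXPA8 (-1.99 ± 0.21 and -2.52 ± 0.21), AT4G02850, AT3G46370, COR15B and ARR15. In total 249 probe sets were higher in both lines and 236 lower in both, against 31.8 and 35.0 for independent lists of these sizes. A further 14 were called in opposite directions against 67.4. Both calls of a probe set rest on 1 shared estimate of its spread. The lists are therefore not fully independent, and these expected numbers may be too low. Of the 3584 probe sets called in K16331, 2850 (79.5%) had the same sign in K19624. The fold changes of all probe sets correlated at r = 0.388 (Spearman 0.328), a correlation across genes, which are not independent replicates. EXPA8 and AT5G22460 were called in both lines under every alternative and with each array left out. Without any 1 of the 3 K19624 arrays or EV_T3 replicate 3 the shared calls fell to between 105 and 165 higher and between 95 and 136 lower, and without EV_T3 replicate 2 the lower count was 149. With each line fitted with its own control only they were 22 and 28.

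**Figure D1:**
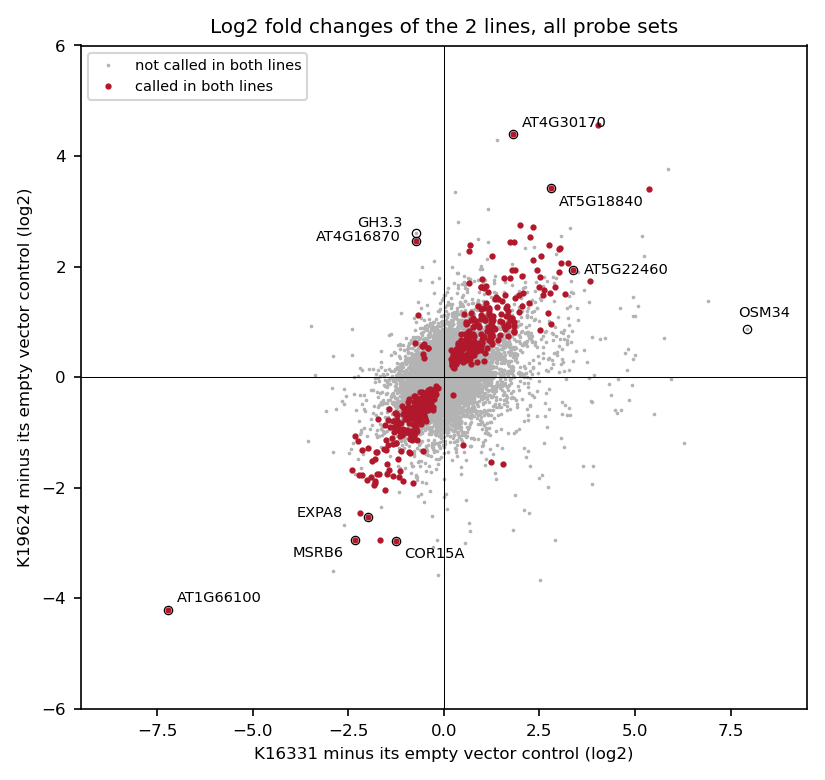
Log2 fold change of each of the 22746 probe sets in K16331 against its empty vector control (x axis) and in K19624 against its own control (y axis), with probe sets called in both lines in red. The 249 probe sets higher in both lines lie at the upper right and the 236 lower in both at the lower left, while OSM34 lies far to the right near the height of 0.87.

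The mean effect of both lines, each against its own control, was called at 1801 probe sets higher and 1958 lower. Of these, 393 and 195 differed at least 2-fold. What a line and its control share cancels in this mean, whereas a deviation of 1 control group alone does not. For comparison, 249 and 236 probe sets were called higher and lower in both lines. AT1G66100 had the largest mean fall, at a log2 fold change of -5.70 ± 0.31 (SE; limma with Benjamini-Hochberg adjusted p = 6.0e-05), followed by AT4G17470 (-3.20), MSRB6 (-2.64), AT1G13650 (-2.32), EXPA8 (-2.26), COR15A (-2.11), COR15B (-2.04) and AT3G46370 (-1.94). AT4G30170 (3.12 ± 0.32) and AT5G18840 (3.11 ± 0.23) rose the most, followed by PAP85 (2.85), the glycosyltransferase gene UGT76B1 (2.81), AT3G05400 (2.78), AT1G51850 (2.69), AT2G04460 (2.68) and AT5G22460 (2.67). Both rankings hold among named genes with all arrays of each line on 1 side of its own control arrays. OSM34, whose K19624 and EV_T3 arrays overlap, is left out by this rule, as are probe sets paired with no gene. Senescence genes rose (3 of 5, and 3 also when adjusted over the list alone; adjusted p = 0.0057; adjusted p = 0.19 with an estimated correlation), and cold response genes fell (2 of 4, and 2 also when adjusted over the list alone; adjusted p = 0.014; adjusted p = 0.35 with an estimated correlation). The photosynthesis list shifted down, with 1 gene higher and 3 lower of 10, and 1 and 6 when adjusted over the list alone (adjusted p = 0.034; adjusted p = 0.62 with an estimated correlation). Chlorophyll synthesis had 5 of 9 genes lower (adjusted p = 1.4e-04; adjusted p = 0.49 with an estimated correlation), and 3 of 13 endoplasmic reticulum stress genes rose (adjusted p = 0.0085; adjusted p = 0.36 with an estimated correlation). No single senescence or chlorophyll synthesis gene passed in K19624 alone, although both lists shifted in the same direction there by camera. Of 15 mitochondrion-encoded genes 4 rose, including cox2 (0.42 ± 0.11) (adjusted p = 0.016; adjusted p = 0.49 with an estimated correlation), a call that ended without K16331 replicate 2 (0.056) or EV_T3 replicate 1 (0.081). The plastid-encoded photosynthesis genes (1 of 35 lower, ycf3) and transcription and translation genes (1 of 19 lower, rpl16) shifted down by camera (adjusted p = 0.0081 and 0.0085; adjusted p = 0.76 and 0.61 with an estimated correlation). By the limma test fry the mitochondrial genes (adjusted p = 0.062) and these 2 plastid groups (0.13 and 0.085) did not pass. In limma AT4G17470 was not called without K16331 replicate 1 (adjusted p = 0.055), K16331 replicate 2 (0.052), EV_T2 replicate 2 (0.057) or K19624 replicate 2 (0.058). A higher signal floor ended the limma calls of AT4G17470 (adjusted p = 0.14), UGT76B1 (0.082) and AT3G46370 (0.080). The photosynthesis list did not pass by camera under quantile normalization (adjusted p = 0.26), with a common median (0.083), without dim probe sets (0.35), with a lower signal floor (0.18) or with a variance trend (0.33), nor by the limma test fry (0.19). Nor did it pass without K16331 replicate 1 (0.067), K19624 replicate 2 (0.059), K19624 replicate 3 (0.068), EV_T3 replicate 2 (0.078) or EV_T3 replicate 3 (0.082).

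The effects of the 2 lines were then compared with each other, as the K19624 effect minus the K16331 effect. OSM34 differed most, with a log2 fold change of 7.93 in K16331 and 0.87 in K19624, a difference of -7.06 ± 0.99 (SE; limma with Benjamini-Hochberg adjusted p = 0.030). GH3.3 differed by 3.34 ± 0.54 (1.66-fold lower in K16331 and 6.08-fold higher in K19624). AT4G16870 was at -0.73 in K16331 and 2.46 in K19624, with EV_T3 the low group, and the orphan gene QQS at -0.58 and 2.00. The other genes with large differences were AT1G29270 (3.28), AT2G07721 (1.79), AT1G75880 (1.78), AT3G18250 (-4.59), AT1G74010 (-4.17), AT5G39520 (-3.40), AT3G57010 (-3.12) and AT2G21820 (-2.98). The difference was called at 239 probe sets, 112 with a positive and 127 with a negative difference, and 153 of them had opposite signs in the 2 lines. Selection for a large difference favours opposite signs by itself. Of the 239, 195 were called in K16331 and 72 in K19624. Among all probe sets, 14 were called in opposite directions in the 2 lines. Line, generation and zygosity differ together, and the medium and the plants per array are only partly stated, so the difference has no single named source. An ordinary linear model called 20 and 21 probe sets and 4 of the 12 named genes, and counts were 33 and 47 with a lower floor, 73 and 58 with a higher one, 48 and 70 with a common median, 231 and 234 with array weights and 218 and 293 without dim probe sets. The counts were 12 and 12 without K19624 replicate 2 and 189 and 229 without EV_T3 replicate 1. Leaving out any other array except EV_T2 replicate 3 moved at least 1 of the counts by over 1.5 times, to between 17 and 71 positive and 28 and 73 negative. AT4G16870 and AT1G75880 were called with each array left out, whereas GH3.3, OSM34 and QQS each lost their call without at least 4 single arrays. Of the lists fixed before the data were examined, the anthocyanin, photosynthesis, jasmonate and heat shock lists were lower in the K19624 effect by camera (adjusted p = 0.047 each; adjusted p = 0.36 each with an estimated correlation). None of their genes passed over all probe sets; adjusted over the list alone, 2 photosynthesis genes and 1 jasmonate gene did, and 1 of the cold response genes, whose list did not pass. With 1 array left out, between 0 and 4 of these lists passed. None passed by camera under quantile normalization, where the photosynthesis list turned the other way (adjusted p = 0.96) and the others were at 0.063. None passed with a variance trend (camera adjusted p from 0.060 to 0.086), nor did the 3 lists still tested without dim probe sets (0.068 each). The photosynthesis list also failed with a lower floor (0.073) and the jasmonate list with a higher one (0.49), and by fry the jasmonate list alone passed.

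EV_T3 was compared with EV_T2, which differ in generation and carry no rice LBD37. Hygromycin is named for the medium of EV_T2 and not for that of EV_T3. OSM34 was at least 117-fold and AT4G16260 at least 49.6-fold higher in EV_T3. AT5G20790 was at the signal floor on all EV_T2 arrays and at least 13.2-fold higher in EV_T3, and GAT1_2.1 and AT5G39520 rose at least 12.9-fold and 11.5-fold and the jasmonate-regulated gene JRG21 by 3.59 ± 0.74 (log2, SE). AT4G16870 fell 11.6-fold, from a log2 signal of 9.73 ± 0.16 to 6.20 ± 0.12 (SD, n = 3), and Fes1B 5.58-fold, AT2G07739 5.29-fold and the auxin response gene IAA30 5.29-fold. AT4G01130 fell 5.28-fold and AT2G06480, at the floor on all EV_T3 arrays, at least 5.64-fold.

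By limma with Benjamini-Hochberg adjustment, 1864 probe sets were higher and 1844 lower in EV_T3, 421 and 290 of them at least 2-fold, with log2 fold changes of 6.87 ± 0.70 (SE) for OSM34 (adjusted p = 8.6e-04) and -3.53 ± 0.11 for AT4G16870 (adjusted p = 6.5e-06). Of 11 histone genes 7 fell, including AT2G28720 (-1.55 ± 0.29) and HTB2 (-1.11 ± 0.24) (camera adjusted p = 1.9e-05; adjusted p = 0.16 with an estimated correlation). Of 9 autophagy genes 6 fell, including ATG3 (-0.49 ± 0.04) (adjusted p = 0.0056; adjusted p = 0.16 with an estimated correlation). Of 11 genes of the NPF nitrate and peptide transporter family 5 rose, including GTR2 (1.01 ± 0.07) and AT3G21670 (1.19 ± 0.20) (adjusted p = 0.0049; adjusted p = 0.16 with an estimated correlation). Of 4 cold, drought and abscisic acid genes COR15A (-1.08 ± 0.30), COR15B (-1.89 ± 0.38) and COR47 (-0.87 ± 0.18) fell, 4 when adjusted over the list alone (adjusted p = 0.0083; adjusted p = 0.26 with an estimated correlation). Of 6 anthocyanin genes UGT78D2 rose (0.81 ± 0.18), 2 when adjusted over the list alone (adjusted p = 0.047; adjusted p = 0.55 with an estimated correlation). In the other fixed lists THI2.1 rose (3.01 ± 0.37, 1 of 3 jasmonate genes), as did PPDK (0.95 ± 0.20, 1 of 5 senescence genes), RCA (0.46 ± 0.06) and LHCB4.1 (0.24 ± 0.04, 2 of 10 photosynthesis genes). Of 6 starch and sugar genes SBE2.2 rose (0.40 ± 0.07) and DPE1 (-1.67 ± 0.19) and PWD (-0.85 ± 0.10) fell. These counts were the same adjusted over the list alone, none of the 6 heat shock or 3 root marker genes passed either way, and none of these 6 lists passed by camera (adjusted p from 0.093 to 0.59). Without EV_T2 replicate 1 the counts were 1160 higher and 1044 lower, without EV_T3 replicate 2 1207 and 1105, and without EV_T2 replicate 2 the lower count was 1225. A fit of these 6 arrays alone gave 855 and 901 and ended the limma calls of GAT1_2.1 (adjusted p = 0.076) and JRG21 (0.065); a higher floor also ended that of GAT1_2.1 (0.13). The anthocyanin call ended without any single array other than EV_T2 replicate 2 and EV_T3 replicate 1 (camera adjusted p from 0.054 to 0.29). It also ended under quantile normalization (0.0501), without dim probe sets (0.18), with a lower floor (0.066), in the 6-array fit (0.14) and by fry (0.11), and the autophagy call without dim probe sets (0.066). Ribosomal RNA differed between the experiments as well. The 25S probe set had a log2 signal of 7.28 ± 0.16 in the T2 and 6.12 ± 0.20 in the T3 experiment (SD, n = 6; two-sided exact permutation p = 0.0022, adjusted p = 0.0043 over 2 probe sets).

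**Figure D2:**
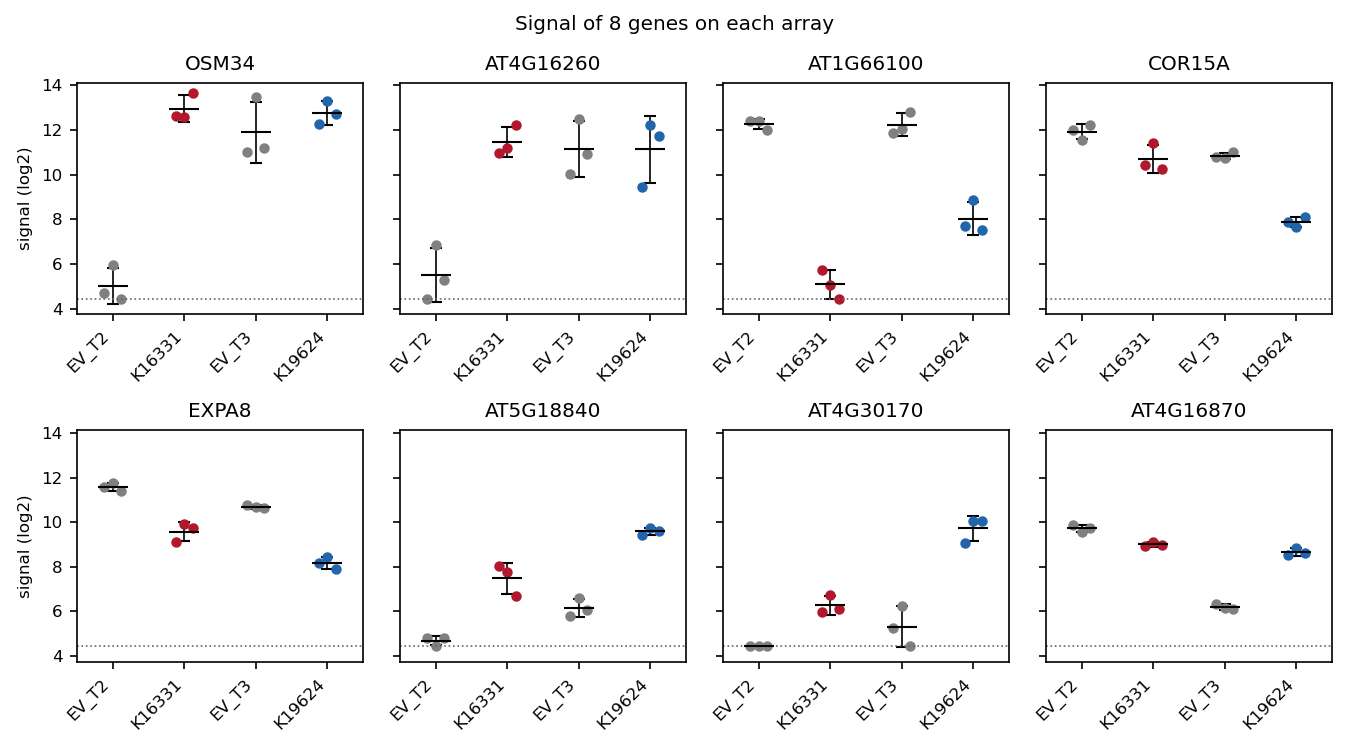
Log2 signal (y axis) of 8 genes on each array, by group (x axis), with a point per array, a bar for the mean, whiskers for 1 SD (n = 3) and a dotted line for the signal floor of 4.45. OSM34 and AT4G16260 were low in EV_T2 and high in the other 3 groups, and AT1G66100 was low in both lines and high in both controls.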

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

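The tests that set explanations against each other in this part were chosen after the results were seen, and the counts over other splits of the arrays were planned beforehand. At 239 probe sets the difference of a line from its own control was not the same in the 2 lines by a test of the difference itself, with 112 positive and 127 negative. The count depends on the model: an ordinary linear model called 20 and 21, and 4 of the 12 genes named here. On the log2 scale, as the K19624 effect minus the K16331 effect, GH3.3 differed by 3.34, AT1G29270 by 3.28, the retrotransposon AT4G16870 by 3.19, QQS by 2.59, AT2G07721 by 1.79 and AT1G75880 by 1.78. On the other side, OSM34 stood at -7.06, AT3G18250 at -4.59, AT1G74010 at -4.17, AT5G39520 at -3.40, AT3G57010 at -3.12 and AT2G21820 at -2.98. In 4 of 100 splits made within each experiment, the real one included, as many probe sets were called (drawn from 200 possible). Such a split can keep the real labels of a single experiment and with them the effect of its line. This share therefore cannot decide whether chance in how the labels fall explains the count. The highest other split called 911, several times the real count, and the source of its calls was not tested.

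Lists called for a difference between the line effects are given with the median of their genes. The median was -0.89 for anthocyanin and flavonoid synthesis, -0.10 for photosynthesis, -1.52 for jasmonate and wounding and -1.17 for heat shock (log2). With an estimated correlation none of these 4 passed by camera (adjusted p = 0.36 each), none passed under quantile normalization, and the photosynthesis list turned the other way there. Among the added lists it was -0.18 for UDP-glycosyltransferases, -0.24 for expansins and xyloglucan hydrolases, -0.24 for iron homeostasis, 0.14 for chlorophyll synthesis and -0.52 for dehydration and late embryogenesis genes. Of the called members, AT3G56360 (-1.61 ± 0.29, SE) belongs to the iron list and OSM34 to the dehydration list. By limma camera with Benjamini-Hochberg adjustment the adjusted p was 7.4e-04, 0.0058, 0.0012, 0.040 and 0.0015 for the 5 added lists. With an estimated correlation it was 0.13, 0.13, 0.20, 0.53 and 0.087. The chlorophyll list did not pass without K16331 replicate 2 (0.18), EV_T2 replicate 1 (0.10), K19624 replicate 1 (0.091), K19624 replicate 3 (0.10), EV_T3 replicate 1 (0.084) or EV_T3 replicate 2 (0.056), nor without dim probe sets (0.082), with a lower floor (0.059), with array weights (0.077) or by fry (0.22).

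K16331 differed from its control at 3584 probe sets and K19624 from its own at 852. Against more spread between the single-plant arrays as the whole cause, the median absolute effect in K16331 was 1.62 times that in K19624 over the probe sets called for the mean effect (1.38 to 1.76 with each array left out). The fit of all 12 arrays also gave both comparisons the same standard error for a probe set. Unequal spread could therefore not lower the K19624 count through that error. The median SD within a group was 0.145 in K16331, 0.136 in EV_T2, 0.141 in K19624 and 0.170 in EV_T3 (log2, all probe sets). Against RNA degradation, the 3 prime minus 5 prime difference of K16331 and EV_T2 differed by -0.0062 (log2, mean of actin, GAPDH and ubiquitin). The other control probe sets gave -0.13, -0.21 and 0.06 for these 3 transcripts, with no overlap of the GAPDH arrays (exact permutation p = 0.1), and none reached the 0.5 set for it. What stays open is that the EV_T2 plants stand apart. Where 1 of the 2 groups lay beyond the 9 other arrays, EV_T2 was that group in 60.1% of the K16331 calls. This was just over the bound of 60% set for it. The same share was 37.8% for EV_T3 among K19624 calls, and 74.3% for EV_T2 among the calls between the 2 controls. OSM34 is a gene with EV_T2 apart. K16331 arrays correlated on average at 0.964 with EV_T2, 0.967 with EV_T3 and 0.974 with K19624. The transgene level, generation, medium and plants per array may also add to the difference and were not tested.

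K16331 and EV_T3 moved the same way when each was set against EV_T2. Of the K16331 calls 1216 were also called in EV_T3 in the same direction, 557 higher and 659 lower, among them OSM34 and AT4G16260 higher and Fes1B lower. The fold changes correlated at 0.545, close to the 0.502 simulated with no change, so neither the correlation nor these counts separate the explanations. Chance values of the 3 shared EV_T2 arrays would add a covariance of 0.0279, while the covariance was 0.147, or 5.27 times that (3.11 to 4.58 with each EV_T2 array left out), which argues against them as the whole cause. A real difference of the EV_T2 plants from the other 3 groups stays open, as does an untested effect shared by rice LBD37 and the T3 plants.

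The 2 lines changed in the same direction more often than independent lists would. Of the K16331 calls 79.5% had the same sign in K19624, which shares no array with them, but another of the 10 splits of the K19624 and EV_T3 arrays gave 82.9%, so these cannot be told apart by this test. That split called 1 probe set, against 852 for the real one. EXPA8, AT1G66100 and AT5G22460 are among the calls of both lines. For K16331 the real split called 3584 probe sets and the highest other 7, for K19624 852 and 16, and for the 2 controls 3708 and 3; in each the real split was 1 of 10, too few splits for a share under 0.05. For the mean effect 1 of 100 splits gave as many calls as the real 3759, the real one itself (highest other 1626). This argues against chance in how the labels fell among these arrays. The splits cannot test whether a whole control group, such as EV_T2, stands apart for a reason other than rice LBD37.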

How the results depend on the processing

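All alternatives in this part were planned beforehand, and none was chosen after the results were seen. For the genes named in the text, calls kept their direction in every alternative in which they were run. Counted once per gene, comparison and setting, with each array left out as a setting, 3134 calls were kept, 577 lost and 0 reversed. Of those kept, 1650 came from leaving out arrays, so these are not numbers of genes. Of list calls, counted in the same way, 767 were kept, 198 lost and 1 reversed. EXPA8 and AT5G22460 were called in both lines throughout. Where a value changed, the cause was not tested unless stated. Settings not listed for a count left it within 1.5 times.

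With the replicate number as a block, K16331 had 1019 higher and 1052 lower, K19624 78 and 76, the mean effect 1167 and 1155, and both lines 46 and 44, with 8 opposite; 1855 of its 2071 K16331 calls and 123 of its 154 K19624 calls were shared with those reported. The limma difference between lines fell to 0 and 0 (3560 at an unadjusted p under 0.05, and 3373 by an ordinary linear model), none of its 12 named genes being called, and 1 fixed list passed for each of the mean effect and the difference. The numbers do not pair the arrays: same-numbered arrays correlated at 0.01, 0.08 and 0.12 in the K16331 experiment and at -0.15, -0.11 and -0.10 in the K19624 experiment, and 3 of 6 arrays correlated best with their own number.

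With each line fitted with its own control only, which leaves fewer arrays to estimate the spread, K16331 had 1227 lower and K19624 60 and 68. EV_T3 against EV_T2 had 855 and 901, both lines 22 and 28 with 1 opposite, and 1 fixed list passed for the controls. Of its 2375 K16331 calls 1999 were shared with those reported, and 101 of its 128 K19624 calls. A minimum of 2-fold leaves fewer by construction: 621 and 333 for K16331, 135 and 107 for K19624, 393 and 195 for the mean effect, 49 and 69 for the difference, 421 and 290 for the controls, and 73 and 46 for both lines with 2 opposite.

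A floor at the 5th percentile, which lets values near background vary, gave K19624 277 and 246, the difference 33 and 47, both lines 149 and 141 with 7 opposite, a correlation of the line effects of 0.246, and 1 fixed list for the controls. A floor at the 40th percentile gave the difference 73 and 58, 6 opposite, a correlation of 0.443 and 8 added lists for the difference. The higher floor left K19624 at 367 and 319, so what signal over background limits was not isolated. Without dim probe sets the difference had 218 and 293 and the correlation was 0.453. In that setting 3 added lists passed for K16331, 2 fixed and 6 added for K19624, 0 fixed for the difference, and 1 fixed and 4 added for the controls. The pseudogene list reversed in the difference there (5.1e-04 by limma camera, 0.0036 after Benjamini-Hochberg).

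For the difference, array weights gave 231 and 234, a common median 48 and 70, and an ordinary linear model 20 and 21, with 7 opposite. Quantile normalization gave 72 higher in the difference, 0 fixed lists there and 1 for the controls. The photosynthesis list reversed in the difference with it (0.844 by limma camera, 0.964 after Benjamini-Hochberg). Of lists, 0 passed with an estimated correlation in any of the 5 contrasts, fixed or added, by limma camera. The limma test fry passed 2 fixed lists for K16331, 2 for K19624 and 1 for the difference, and camera with a variance trend 0 fixed for the difference. The minimum fold and the ordinary linear model do not apply to list tests and were not run for them.

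With each array left out in turn, which leaves 2 in its group, K16331 had 1006 to 1629 higher and 1025 to 1946 lower, and K19624 170 to 498 and 163 to 490. The mean effect had 1348 to 1794 and 1398 to 1861, the difference 12 to 189 and 12 to 229, and the controls 1160 to 1836 and 1044 to 1875. Both lines had 105 to 240 and 95 to 240, with 3 to 37 opposite and a correlation of 0.318 to 0.455. Fixed lists numbered 1 to 1 for K16331, 2 to 4 for K19624, 2 to 4 for the mean effect, 0 to 4 for the difference and 1 to 4 for the controls. Added lists numbered 2 to 8, 3 to 4, 4 to 7, 4 to 7 and 5 to 8 in the same order.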

Other observations

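Some list members were called in both lines in the same direction; those named here follow the rule for lists, and no test in this part was chosen after the result was seen. The glucosinolate transporter gene GTR2 rose by 1.05 ± 0.07 in K16331 and 0.72 ± 0.07 in K19624 (log2, SE, n = 3), and the glutathione transferase gene GSTU27 2.29-fold and 1.59-fold. DELTA-OAT, an ornithine aminotransferase gene, rose by 0.89 ± 0.10 and 0.54 ± 0.10, SWEET7 by 1.77 ± 0.35 and 1.94 ± 0.35, and bHLH115 by 0.62 ± 0.05 and 0.43 ± 0.05. The jasmonate-linked transcription factor gene ORA47 was at -1.33 ± 0.30 and -1.79 ± 0.30, and the sterol glycosyltransferase gene UGT80B1 at -0.74 ± 0.12 and -0.64 ± 0.12. All of these were called in both lines. Called in K16331 were also LEA4-5 (3.80 ± 0.58), THI2.2 (-2.16 ± 0.27), IAA29 (-2.12 ± 0.55), IAA30 (-1.03 ± 0.26) and IAA34 (-0.96 ± 0.27), and in K19624 the expansin gene EXPA4 (2.30-fold lower).

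Between the 2 controls, further gene groups differed by limma camera with Benjamini-Hochberg adjustment. Of 19 plastid-encoded transcription and translation genes 5 were lower in EV_T3, including rpoB (-1.09 ± 0.11; adjusted p = 0.0016; adjusted p = 0.55 with an estimated correlation). Of 35 plastid-encoded photosynthesis genes 5 were lower and 2 higher, including psbT (-0.91 ± 0.12) and psaJ (0.56 ± 0.09; adjusted p = 0.016; adjusted p = 0.61 with an estimated correlation), a call that ended without EV_T2 replicate 1 (0.15) or EV_T3 replicate 1 (0.065). Of 10 plastid-encoded ndh genes 3 were lower, including ndhJ (-1.50 ± 0.18; adjusted p = 0.045; adjusted p = 0.61 with an estimated correlation). Of 51 UDP-glycosyltransferase genes 8 were higher, including UGT84A3 (1.82 ± 0.20; adjusted p = 0.018; adjusted p = 0.35 with an estimated correlation), which ended without EV_T3 replicate 3 (0.069). Of 16 defensin, thionin and jasmonate-linked genes THI2.1 and JRG21 were higher (adjusted p = 0.045; adjusted p = 0.35 with an estimated correlation). The ndh call ended without any of K16331 replicates 1 and 2, EV_T2 replicate 1 and EV_T3 replicates 1 and 2 (camera adjusted p from 0.058 to 0.22). The defensin call ended without any of K16331 replicates 1 and 2, EV_T2 replicates 1 and 2, K19624 replicates 2 and 3 and EV_T3 replicates 1 and 3 (camera adjusted p from 0.051 to 0.15). Without dim probe sets the plastid-encoded photosynthesis, ndh and defensin calls ended by camera (adjusted p from 0.066 to 0.083). The ndh call also ended under quantile normalization (0.055), the defensin call with a higher floor (0.10) and in the 6-array fit (0.10), and the photosynthesis call by fry (0.16). AT2G26690 was higher (0.82 ± 0.15) and GI lower (-1.12 ± 0.16) in EV_T3.

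Some probe sets that the platform table pairs with no gene changed as much as the named ones. An example, chosen after its values were seen like those that follow, rose by 4.02 ± 0.20 in K16331 and 4.56 ± 0.20 in K19624 (log2, SE; limma adjusted p = 6.5e-05 and 4.8e-05), and another was at -2.01 ± 0.11 and -1.86 ± 0.11. In K19624 a different probe set rose by 2.80 ± 0.13 and a further one was at -3.07 ± 0.14, with 0.38 and -0.29 in K16331. GAT1_2.1 has 2 probe sets, at 0.90 and 0.00 in K16331 and at -0.84 and -0.29 in K19624, none of them called. The 5S ribosomal RNA probe set had a log2 signal of 8.92 ± 0.25 in K16331 and 9.55 ± 0.21 in EV_T2, and of 8.58 ± 0.21 in K19624 and 7.55 ± 0.62 in EV_T3 (SD, n = 3), so it was lower than the control in 1 line and higher in the other. For the other set of control probe sets, the 3 prime minus 5 prime difference was -0.58 for actin and -0.33 for GAPDH in EV_T3 minus EV_T2 (log2, n = 3; exact permutation p = 0.1 for each, the smallest possible).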
